A study of Homo sapiens with 9 samples.

How the data were processed

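Total RNA of COR-L279 cells after 24 h in DMSO, 0.5 µM JQ1 or 1.5 µM JQ1 was measured in 3 libraries per group, 9 in all. Per the labels, RNA was isolated with an RNeasy kit and made into stranded TruSeq libraries, and the authors' processing notes name cutadapt, STAR, RSEM and the genome build hg19. Versions, settings, the annotation release and the strand setting of the counting are not given in the sources used here, so values of genes that overlap others on either strand are uncertain. Gene positions are not given, because the annotation at hand is of another genome build.

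The main values are the authors' deposited normalized counts, a signal per gene and library made by dividing gene counts by 1 DESeq2 size factor per library. They were checked against that unit: with 1 factor per library, 100% of the values came out as whole reads within a tolerance of 0.001, and the whole reads summed to between 60721187 (0.5 µM replicate 2) and 88482001 (DMSO replicate 2). The table holds 17518 genes, and each of them had at least 0.5 CPM (read counts scaled to library size) in at least 2 libraries. The authors also deposited FPKM values from RSEM for 57820 genes, rounded to 2 decimals and scaled for transcript length and library size. These served as an alternative and for genes outside the main table. Of the genes in the main table, 16970 matched GENCODE release 29 by Ensembl ID, which gave their type. No file held columns of other samples.

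Differential expression was tested with limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with a mean-variance trend, all 9 libraries in 1 fit and no replicate block. Genes needed a normalized count of at least 10 in at least 3 libraries, which left out 4 and kept 17514. Tests were two-sided, and p values were adjusted by Benjamini-Hochberg within each comparison, with 0.05 as the threshold. On the log2(value + 1) scale the fold changes of genes with low counts are understated. Fold changes are relative to the bulk of genes, as no spike-in was used. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with a correlation estimated per list. The overlap of the doses was set beside 20 simulations of unchanged groups that share their controls.

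The 32 lists, the rule for named genes, the tests and all alternatives but 1 were chosen before the data were examined. Genes are named if they belong to a fixed set of SCLC, MYC, BET and neuroendocrine genes. Also named are the 6 genes with the largest positive and the 6 with the largest negative log2 fold changes at each dose, and the 3 of each sign between the doses. These had to pass the test with a mean normalized count of at least 100, no overlap between the groups, and a symbol that is not a clone or pseudogene name. For each list, up to 3 members past the test at 1.5 µM with the largest changes and a mean of at least 20 are named as well. The alternatives were other pseudocounts (0.1 and 5), no filter or a minimum of 50, the FPKM values (log2 of the value + 0.1, at least 0.5 in 3 libraries), TMM and upper-quartile scaling, limma without trend or with library weights, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, a fit to the 6 libraries compared, a replicate block, and each library left out in turn. The alternative added after seeing the data leaves out the 3 libraries that held H19 and SLC2A3.

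The test was checked on simulated data, with 200 genes set to change by a known fold in data of the same spread. For 0.5 µM against DMSO it recovered 70% of the genes changed 1.25-fold, 58% of those changed 1.5-fold, 76% at 2-fold and 96% at 4-fold, with 12 false calls among 17440 genes. For 1.5 µM it recovered 46%, 64%, 88% and 94%, with 4 false calls among 17442 genes. No recovered gene had the wrong direction. Each share rests on 50 genes and holds where few genes change. In the data most genes passed, which loosens the adjusted threshold, so the shares do not give the recovery there. Replicates differed by more than counting error: chi-square per degree of freedom between libraries of a group was 3.41 to 31.2, the highest for 0.5 µM replicate 2 against replicate 3. Mitochondrial transcripts took 3.2% to 3.75% of the reads and ribosomal protein genes 4.33% to 5.36%.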

Results

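COR-L279 is an established human small cell lung cancer (SCLC) line of the SCLC-N subtype, which is defined by the neurogenic transcription factor NEUROD1. JQ1 is a small molecule that displaces the BET bromodomain proteins from acetylated chromatin, and the study asked how the transcriptome of these cells responds to it. Cells were treated for 24 h with DMSO, the vehicle, or with JQ1 at 0.5 or 1.5 µM. Each group held 3 libraries, called biological replicates in the labels, which makes 9 libraries. Total RNA was sequenced, and expression is given as normalized read counts of 17514 tested genes. The 3 DMSO libraries held 67520035, 88482001 and 73237162 reads in genes, the 0.5 µM libraries 68162757, 60721187 and 62948031, and the 1.5 µM libraries 69286187, 80985676 and 70307954, each in the order of the replicate numbers.

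The first principal component of expression held 71.5% of the variance and parted the DMSO libraries (-82.2 to -78.4) from the 0.5 µM libraries (26.5 to 33.7) and the 1.5 µM libraries (47.0 to 51.01). The second component held 9.99% and set 0.5 µM replicate 2 (-50.6) apart from the other 8 libraries (-11.3 to 25.2). In 3 of the JQ1 libraries, 0.5 µM replicate 3 and 1.5 µM replicates 1 and 2, H19, an imprinted noncoding RNA, reached 1563, 2071 and 1476 normalized counts. The DMSO libraries held 63.8 to 82.8 normalized counts of H19, and the other 3 JQ1 libraries 1.04, 8.22 and 2.05. SLC2A3, a glucose transporter, followed the same libraries with 489, 479 and 390 normalized counts against at most 3.52 elsewhere. Both genes were chosen after their values were seen. Genes whose values moved with these 3 libraries are named as such in what follows.

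The comparison of 0.5 µM JQ1 with DMSO asked which genes respond to the lower dose. HEXIM1 (ENSG00000186834.2), an inhibitor of the elongation factor P-TEFb and a widely used marker of BET inhibition, rose 4.87-fold, from 1125 ± 21.7 to 5487 ± 75.2 normalized counts (SD, n = 3). NEUROD1 (ENSG00000162992.3) rose 1.35-fold, a log2 fold change of 0.44 ± 0.028 (SE, limma adjusted p = 2.67e-07). MYC, a growth-promoting transcription factor, fell from 31636 ± 76.2 to 22559 ± 216 normalized counts. DLL3, an inhibitory Notch ligand, fell from 3499.5 ± 56.7 to 1515 ± 40.1 normalized counts, and SSTR2, a somatostatin receptor, from 3608 ± 89.2 to 1256 ± 24.7; both proteins are followed as drug targets in SCLC. For these genes and for every other gene named below as one that rose or fell in a comparison, all 3 libraries of one group lay above all 3 of the other.

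Among the other genes fixed for naming, the BET genes BRD2 and BRD3 rose by log2 fold changes of 0.97 ± 0.035 (SE) and 0.42 ± 0.078. BCL2L11, which encodes the pro-apoptotic protein BIM, rose from 2927 ± 55.1 to 5544 ± 276 normalized counts. SERPINI1, a neuronal serine protease inhibitor, rose from 1994 ± 97.4 to 5703 ± 935, and MYCL from 545 ± 15.9 to 869 ± 47.7. The neuroendocrine markers CHGA (log2 fold change -0.41 ± 0.029) and SYP (-0.28 ± 0.030) fell. LSAMP, a neural adhesion molecule, had a log2 fold change of -0.16 ± 0.043 (adjusted p = 0.00706). LSAMP did not pass the test on FPKM values (-0.11, adjusted p = 0.257; range over the alternatives 0.0013 to 0.257) or, with fewer samples, without the 3 libraries with H19 and SLC2A3 (-0.145, adjusted p = 0.0542). INSM1, a neuroendocrine transcription factor, had 0.0031 ± 0.044 (adjusted p = 0.954), with a negative sign under upper-quartile scaling (-0.051) and on FPKM values (-0.038). INSM1 was also negative without DMSO replicate 2 (-0.005), not above 0 without DMSO replicate 3, and negative without 0.5 µM replicate 1 (-0.031) or 3 (-0.015), and it passed with library weights alone (0.07, adjusted p = 0.0116; range over the alternatives 0.0116 to 0.995). YAP1 moved with the 3 libraries that held H19 and SLC2A3 (log2 fold change 1.32 ± 1.16, adjusted p = 0.328). It stood at 148 normalized counts in 0.5 µM replicate 3 and at 10.1 to 12.9 in the DMSO libraries and the other 0.5 µM libraries.

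The largest rises at 0.5 µM under the naming rule were those of histone genes. HIST2H4A and HIST2H4B are near-identical copies whose reads cannot be assigned with certainty, so their sum is given: it rose from 379.8 ± 10.1 in DMSO to 4605 ± 107 normalized counts (SD, n = 3), 12.1 times as many. The sum of the near-identical HIST2H3A and HIST2H3C went from 31.8 ± 5.13 to 735 ± 76.0 normalized counts. HIST1H2BD rose by a log2 fold change of 3.35 ± 0.055 (SE, limma adjusted p = 9.96e-11) and TEX14, a gene of germ cell intercellular bridges, by 3.33 ± 0.13. The largest falls included CDH19, a cadherin, from 1334 ± 63.5 to 52.4 ± 3.14 normalized counts, and LOXL4, a lysyl oxidase, from 2968 ± 18.8 to 128 ± 11.8. TP63, a transcription factor of squamous epithelium, fell from 613 ± 44.9 to 30.3 ± 8.64. SLC38A5, an amino acid transporter, fell by 3.98 ± 0.096 on the log2 scale and VSIG8 by 3.96 ± 0.36. ZACN, a ligand-gated ion channel gene, had 979, 383 and 234 normalized counts in the DMSO libraries and 1.13 to 4.15 at 0.5 µM. As the strand setting of the counting is not given in the sources used here, values of genes that overlap others are uncertain.

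In all, 12255 genes changed at 0.5 µM (limma, Benjamini-Hochberg adjusted p under 0.05), 6174 higher and 6081 lower. Of these, 845 were higher and 1765 lower by at least 2-fold, and the median size of the changed log2 values was 0.52. The libraries of the groups did not overlap in 72.6% of the tested genes, where chance gives 10%. The values are relative to the bulk of genes, since the normalization has no external standard.

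**Figure D1:**
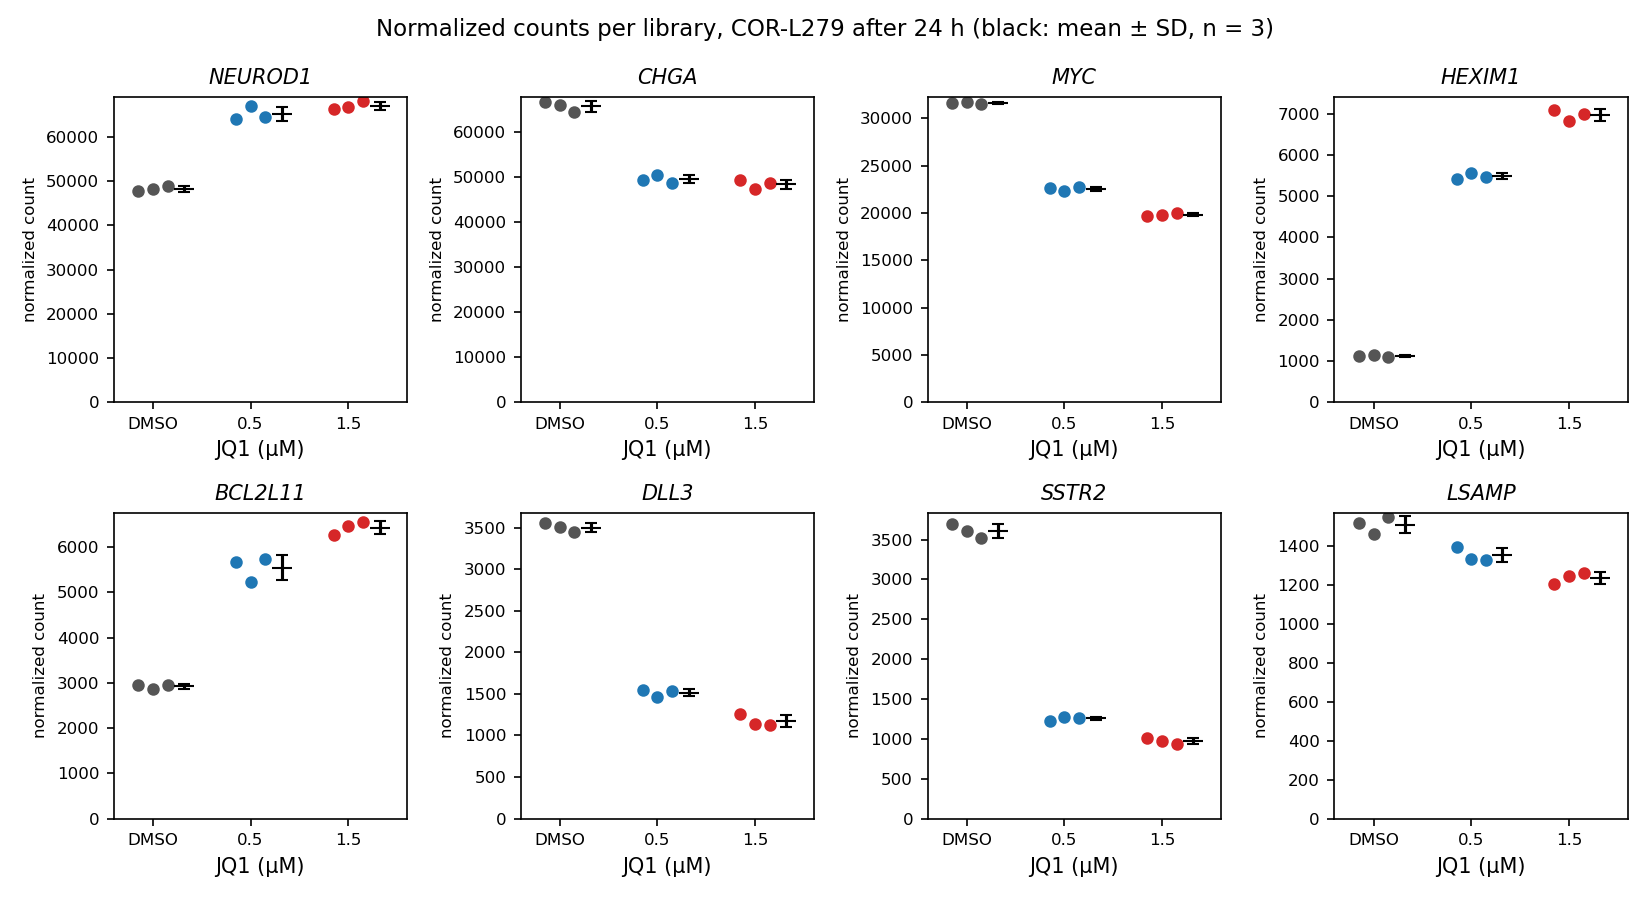
Normalized counts (y axis, from 0) of 8 named genes in each library after 24 h of DMSO or of JQ1 at 0.5 or 1.5 µM (x axis), with the mean ± SD of the 3 libraries in black. HEXIM1 stood at 1125 normalized counts in DMSO, 5487 at 0.5 µM and 6976 at 1.5 µM, while DLL3 stood at 3499.5, 1515 and 1176.

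The comparison of 1.5 µM JQ1 with DMSO asked for the response to the higher dose. HEXIM1 rose 6.2-fold (log2 fold change 2.63 ± 0.032, SE, n = 3, limma adjusted p = 1.26e-11), to 6976 ± 144 normalized counts (SD). NEUROD1 rose 1.39-fold (0.48 ± 0.028). MYC fell to 19819 ± 159 normalized counts (-0.67 ± 0.024), DLL3 to 1176 ± 72.0 (-1.57 ± 0.048) and SSTR2 to 972 ± 36.3 (-1.89 ± 0.042). BCL2L11 rose to 6427 ± 147 normalized counts, a log2 fold change of 1.13 ± 0.040.

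At this dose BRD2 rose by 1.10 ± 0.035 (SE) and BRD3 by 0.61 ± 0.078 on the log2 scale. SERPINI1 (1.59 ± 0.093) and MYCL (0.60 ± 0.060) rose, and CHGA (-0.44 ± 0.029) and SYP (-0.35 ± 0.030) fell. LSAMP fell by 0.29 ± 0.043 (adjusted p = 0.000114), but had -0.12 on FPKM values (adjusted p = 0.189; range over the alternatives 3.05e-07 to 0.189). INSM1 had 0.0070 ± 0.044 (adjusted p = 0.892), with a negative sign under upper-quartile scaling (-0.044), on FPKM values (-0.053). The sign was negative too without DMSO replicate 2 (-0.001) or 1.5 µM replicate 3 (-0.009). YAP1 stood at 178 and 117 normalized counts in 1.5 µM replicates 1 and 2, which held H19 and SLC2A3, and at 7.18 in replicate 3 (log2 fold change 2.20 ± 1.16, adjusted p = 0.11). Without 1.5 µM replicate 3 YAP1 had 3.58 (adjusted p = 0.00583, within a range of 0.00583 to 0.352 over the alternatives). With no library of either group left out, YAP1 passed by edgeR (adjusted p = 0.0271) and DESeq2 (adjusted p = 0.0159). It passed also by limma with library weights (adjusted p = 0.0441) or fitted to the 6 libraries compared (adjusted p = 0.0462). Without the 3 libraries that held H19 and SLC2A3 it had -0.569. BCL2, MYCN and POU2F3 were not among the genes of the normalized count table, which holds genes with at least 0.5 CPM (read counts scaled to library size) in at least 2 libraries.

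The histone genes again led the rises under the naming rule. The sum of HIST2H4A and HIST2H4B rose to 6703.5 ± 63.6 normalized counts (17.7 times DMSO; SD, n = 3), and that of HIST2H3A and HIST2H3C to 1204 ± 91.3. EPAS1, which encodes a hypoxia-inducible factor, rose at both doses (log2 fold change 3.14 ± 0.66 and 4.25 ± 0.66) and moved with the 3 libraries that held H19 and SLC2A3. These 3 libraries had 427, 584 and 429 normalized counts, the other JQ1 libraries 82.0, 92.7 and 131, and the DMSO libraries 12.4 to 21.3. Genes with the largest falls included CDH19 (25.9 ± 8.85 normalized counts, SD), ZACN (17.7 ± 22.2) and SH3TC1 (from 604 ± 24.1 to 17.4 ± 7.42). KRT15, a keratin of basal epithelium, fell from 889 ± 61.5 to 25.7 ± 8.91 normalized counts and C2orf54 from 563 ± 16.0 to 17.4 ± 3.82. BRS3, an orphan receptor of the bombesin family, fell from 1627 ± 37.3 to 52.4 ± 10.6 normalized counts.

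At 1.5 µM, 12806 genes changed (limma, Benjamini-Hochberg adjusted p under 0.05), 6468 higher and 6338 lower. Of these, 1235 were higher and 2066 lower by at least 2-fold, with a median size of 0.58 among the changed log2 values. The libraries of the groups did not overlap in 81.7% of the tested genes, against 10% by chance.

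The 32 gene lists fixed for these comparisons were followed at both doses, and 28 of them had enough tested genes for camera. At 0.5 µM, 13 lists passed camera (adjusted p under 0.05), 5 of them up and 8 down, and 8 lists did so at 1.5 µM, 3 up and 5 down. Histone genes, which package replicating DNA, had the largest median of the 28 lists: of 40 tested, 38 rose at 0.5 µM and 40 at 1.5 µM. None fell by limma, and 0 were lower at an unadjusted p under 0.05. The median log2 fold changes of the list were 1.91 and 2.51 (camera adjusted p = 1.75e-11 and 6.3e-12; adjusted p = 0.0352 and 0.0319 with an estimated correlation). HIST1H2AC rose from 324 ± 13.2 to 3220 ± 283 and 4362 ± 73.4 normalized counts (SD, n = 3), and HIST3H2BB from 2.55 ± 1.66 to 63.1 ± 4.88 and 108 ± 11.8. Histone genes together took 144 ± 1.80 ppm of all reads in DMSO, 559 ± 27.2 ppm at 0.5 µM and 713 ± 2.04 ppm at 1.5 µM. All 11 genes listed as reported to rise under BET inhibitors rose at both doses, with medians of 1.68 and 2.14 (camera adjusted p = 1.16e-07 and 3.26e-07; adjusted p = 0.0695 and 0.0793 with an estimated correlation). Of these 11, 6 are histone genes, and HIST2H2BE (2.51 ± 0.037 and 2.89 ± 0.037, SE) and HEXIM1 are members. All 4 tested genes listed as reported to fall did so at both doses, too few for camera. They are MYC, CDK6, CCND2, a D-type cyclin (-2.94 ± 0.34 and -2.62 ± 0.34), and TERT, the catalytic subunit of telomerase (-1.26 ± 0.085 and -1.55 ± 0.085). CCND2 moved with the 3 libraries that held H19 and SLC2A3. These had 112, 86.6 and 103 normalized counts of CCND2, against 37.6 to 60.2 in the other JQ1 libraries and 466 to 517 in DMSO. Of 24 genes of BET proteins and transcription elongation, 13 rose and 4 fell at 0.5 µM, and 15 rose and 6 fell at 1.5 µM (median log2 fold change 0.14 and 0.20, camera adjusted p = 0.0807 and 0.0843). MLLT3, a reader of acylated histones, rose (0.91 ± 0.041 and 1.05 ± 0.041), and HEXIM2, a relative of HEXIM1, fell (-0.47 ± 0.11 and -0.98 ± 0.11).

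**Figure D2:**
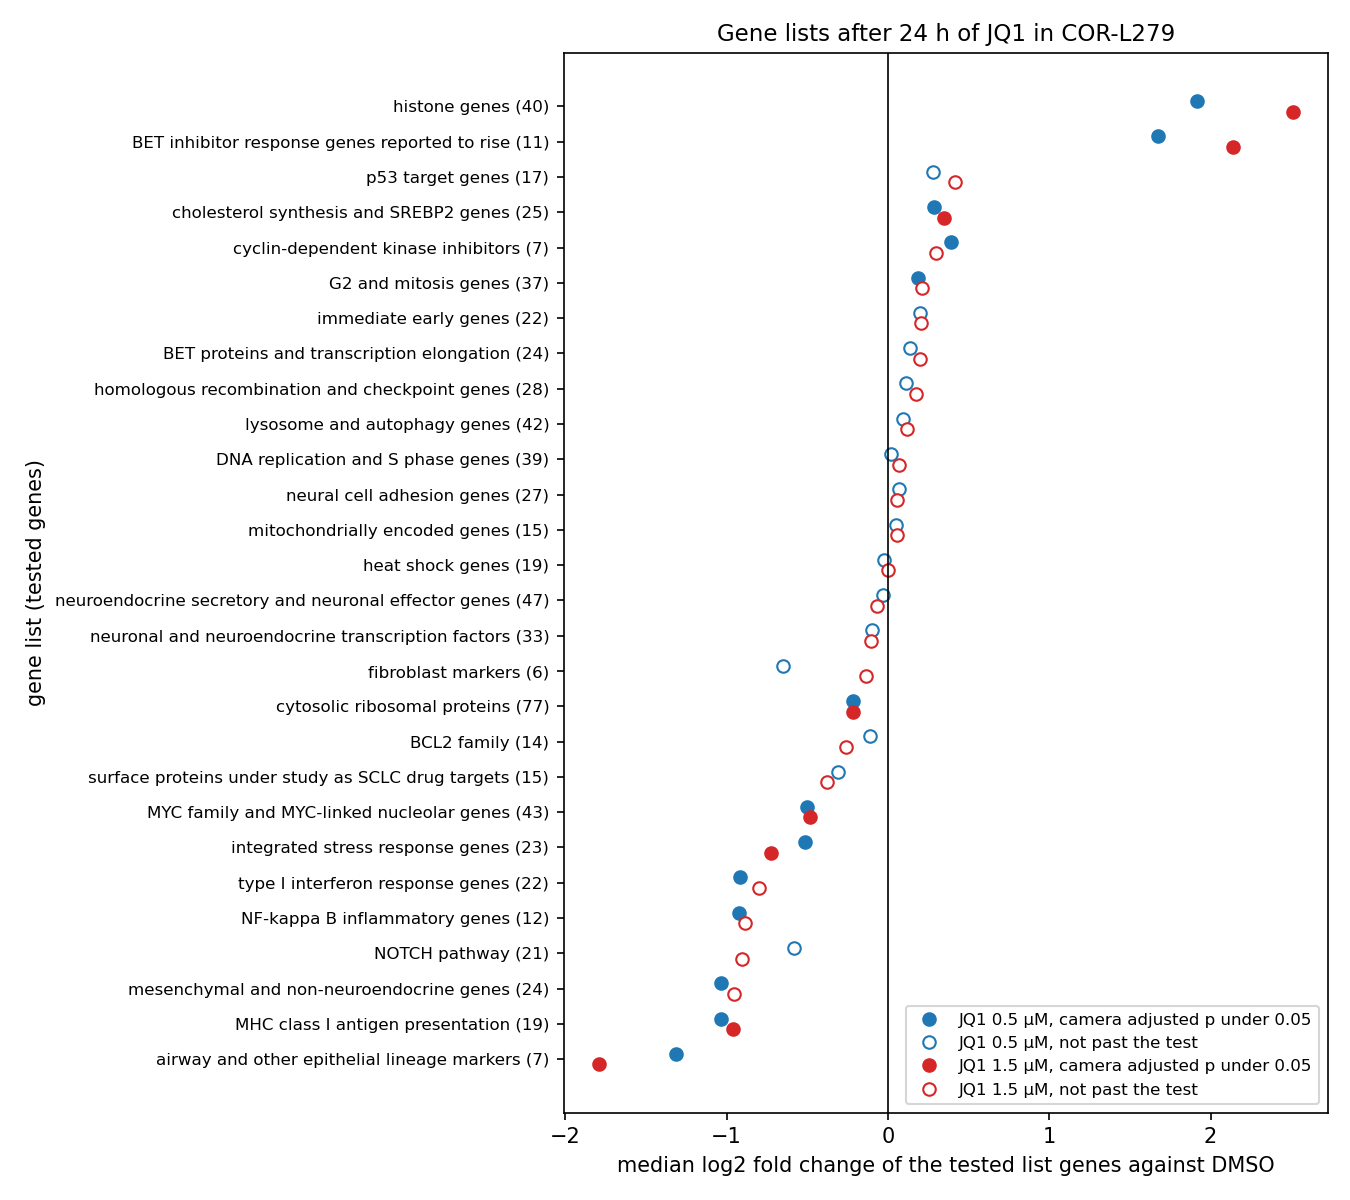
Median log2 fold change against DMSO (x axis) of the tested genes of 28 gene lists (y axis, number of tested genes in brackets) at 0.5 µM (blue) and 1.5 µM JQ1 (red), with filled points for camera adjusted p under 0.05. Histone genes stood at 1.91 and 2.51, and MHC class I genes at -1.03 and -0.96.

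Genes of neuroendocrine identity moved in both directions, as did tested genes at large. Of all 17514, 6174 rose and 6081 fell at 0.5 µM, and 6468 rose and 6338 fell at 1.5 µM. Among the SCLC subtype regulators, NEUROD1 rose and YAP1 did not pass the test, at both doses. Of 33 neuronal and neuroendocrine transcription factors, 12 rose and 15 fell at 0.5 µM, and 14 rose and 16 fell at 1.5 µM (median log2 fold change -0.10 and -0.11, camera adjusted p = 0.646 and 0.441). NEUROD6, a relative of NEUROD1, fell from 135 ± 24.0 to 4.47 ± 1.27 and 2.35 ± 1.27 normalized counts (SD, n = 3). FOXA2, a pioneer factor of endoderm, fell from 1062 ± 27.8 to 300.4 ± 8.14 and 264 ± 16.9 normalized counts. RXRG, a retinoid receptor, also fell (-2.13 ± 0.16 and -2.50 ± 0.16, SE). Of 47 secretory and neuronal effector genes, 19 rose and 19 fell at 0.5 µM (median -0.031, mean 0.0037, camera direction up, adjusted p = 0.893), and 16 rose and 20 fell at 1.5 µM (median -0.068, adjusted p = 0.643). PCSK1, a prohormone convertase, fell from 67032 ± 2079 to 18701 ± 592 and 15767 ± 407 normalized counts. DDC, which makes dopamine and serotonin, fell from 11275 ± 56.7 to 4709 ± 197 and 3258 ± 63.1, and GRP, a growth-promoting neuropeptide, from 107 ± 6.80 to 28.99 ± 5.50 and 21.1 ± 2.36. Among 27 neural adhesion genes 12 rose and 13 fell at 0.5 µM and 13 rose and 13 fell at 1.5 µM. Their medians (0.070 and 0.059) were positive, with -0.0025 and -0.0058 on FPKM values, while their means (-0.18 and -0.22) and camera pointed down (adjusted p = 0.927 and 0.872). CADM2 rose (2.24 ± 0.081 and 2.604 ± 0.081), while OPCML (-2.24 ± 0.28 and -2.50 ± 0.28) and CNTN2 (-1.69 ± 0.085 and -2.08 ± 0.085) fell.

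Of 21 NOTCH pathway genes, 6 rose and 12 fell at each dose, with medians of -0.58 and -0.90 (camera adjusted p = 0.0698 and 0.0815). The ligand genes DLL1 (-2.37 ± 0.072 and -2.46 ± 0.072, SE, n = 3) and DLL4 (-2.04 ± 0.27 and -2.48 ± 0.27) fell, as did HES1 (-2.39 ± 0.20 and -2.65 ± 0.20), a repressor induced by Notch. Among 15 surface proteins under study as SCLC drug targets, 6 rose at each dose, and 8 and 9 fell (medians -0.31 and -0.38, camera adjusted p = 0.41 and 0.333). CEACAM5, an epithelial adhesion protein, fell from 249 ± 19.3 to 26.4 ± 6.19 and 19.2 ± 4.10 normalized counts (SD). NTRK2, a neurotrophin receptor, fell from 588 ± 41.2 to 104 ± 22.4 and 99.7 ± 15.9, and GRIN1, a glutamate receptor subunit, from 457 ± 33.7 to 108 ± 14.1 and 102 ± 6.07. Of 24 mesenchymal and non-neuroendocrine genes, 5 rose and 15 fell at each dose (medians -1.03 and -0.95, camera adjusted p = 0.0411 and 0.0513). The call at 0.5 µM was lost with an estimated correlation (adjusted p = 0.221) and without 0.5 µM replicate 2 (adjusted p = 0.0664; range over the alternatives 1.72e-06 to 0.221). AMOTL2 (-1.82 ± 0.059 and -2.10 ± 0.059) and CCND1 (-1.40 ± 0.34 and -1.53 ± 0.34) fell. MYOF fell at both doses (-2.70 ± 0.77 and -2.07 ± 0.77, adjusted p = 0.0326 at 1.5 µM) and moved with the 3 libraries that held H19 and SLC2A3. These had 98.0, 110.3 and 106 normalized counts of MYOF against 14.4 to 27.0 in the other JQ1 libraries. At 1.5 µM MYOF did not pass without DMSO replicate 1, 2 or 3 (-2.189, -2.051 and -1.957, adjusted p = 0.0588, 0.0727 and 0.0847) or 1.5 µM replicate 3 (-1.12, adjusted p = 0.114), within a range of 0.000119 to 0.114 over the alternatives.

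Genes of ribosome production fell together. Of 43 MYC family and MYC-linked nucleolar genes, 2 rose (MYCL and ODC1) and 39 fell at 0.5 µM, and 2 rose and 41 fell at 1.5 µM. The list passed at both doses (medians -0.50 and -0.48, camera adjusted p = 5.83e-10 and 2.72e-09; adjusted p = 0.0434 and 0.0517 with an estimated correlation). NOP16 fell from 1900 ± 33.4 to 804 ± 30.6 and 697 ± 31.6 normalized counts (SD, n = 3). WDR74 (-1.04 ± 0.048 and -1.25 ± 0.048, SE) and PPAN (-1.01 ± 0.042 and -1.16 ± 0.042) fell. Of 77 cytosolic ribosomal protein genes, 6 rose at each dose, and 52 and 53 fell (medians -0.22 and -0.21, camera adjusted p = 0.000132 and 0.000121; adjusted p = 0.545 and 0.525 with an estimated correlation). Replication genes did not move as a list: of 39 S phase genes, 15 rose and 13 fell at 0.5 µM and 18 rose and 15 fell at 1.5 µM. Their median was 0.022 at 0.5 µM, with -0.032 under upper-quartile scaling and -0.023 on FPKM values (camera adjusted p = 0.817). It was 0.067 at 1.5 µM, with -0.042 on FPKM values and a mean of -0.016 (camera direction up, adjusted p = 0.844). E2F2 (-1.06 ± 0.070 and -1.34 ± 0.070) and E2F8 (-0.47 ± 0.076 and -0.72 ± 0.076) fell, and CLSPN, a checkpoint mediator, rose (0.59 ± 0.047 and 0.78 ± 0.047). Of 37 G2 and mitosis genes, 23 and 24 rose and 7 and 10 fell (medians 0.19 and 0.21, camera adjusted p = 0.0377 and 0.0707). The G2 and mitosis call at 0.5 µM was lost with an estimated correlation (adjusted p = 0.718) and without 0.5 µM replicate 2 (adjusted p = 0.0719; range over the alternatives 0.00974 to 0.718). ASPM (0.72 ± 0.055 and 0.87 ± 0.055), HMMR (0.60 ± 0.069 and 0.63 ± 0.069) and BUB1 (0.50 ± 0.036 and 0.56 ± 0.036) rose.

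Of 7 cyclin-dependent kinase inhibitors, 5 rose at 0.5 µM and 4 at 1.5 µM, and none fell by limma, with 0 lower at an unadjusted p under 0.05. The list passed at 0.5 µM (medians 0.39 and 0.30, camera adjusted p = 0.0349 and 0.162; adjusted p = 0.221 at 0.5 µM with an estimated correlation). CDKN2D rose from 2331 ± 75.2 to 5821 ± 407 and 6152 ± 130.1 normalized counts (SD, n = 3). CDKN2C rose from 24162 ± 200.3 to 48563 ± 6446 and 46363 ± 431 normalized counts, and CDKN2B by 0.42 ± 0.051 and 0.51 ± 0.051 (SE). Of 14 BCL2 family genes, 4 rose at each dose, BCL2L11 among them, and 7 and 8 fell (medians -0.11 and -0.26, camera adjusted p = 0.48 and 0.315). The pro-apoptotic BIK (-1.56 ± 0.14 and -1.94 ± 0.14) and BOK (-1.19 ± 0.070 and -1.43 ± 0.070) fell. Of 28 homologous recombination and checkpoint genes, 15 and 16 rose and 7 fell at each dose (medians 0.11 and 0.17, camera adjusted p = 0.0698 and 0.0707). BRCA2 (0.74 ± 0.047 and 1.07 ± 0.047), XRCC2 (0.84 ± 0.041 and 1.05 ± 0.041) and BARD1 (0.68 ± 0.074 and 0.86 ± 0.074) rose. Of 17 p53 target genes, 11 rose and 4 fell at each dose (medians 0.28 and 0.42, camera adjusted p = 0.121 and 0.123). TP53INP1 (1.47 ± 0.079 and 1.72 ± 0.079) and RRM2B (0.95 ± 0.040 and 1.12 ± 0.040) rose and AEN (-1.07 ± 0.040 and -1.18 ± 0.040) fell.

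Among metabolic and stress genes, 18 of 25 cholesterol synthesis genes rose at each dose and 4 and 5 fell (medians 0.28 and 0.35, camera adjusted p = 0.00115 and 0.00164; adjusted p = 0.0458 and 0.0581 with an estimated correlation). TM7SF2 (1.02 ± 0.039 and 1.22 ± 0.039, SE), INSIG1 (1.01 ± 0.028 and 1.21 ± 0.028) and LSS (0.74 ± 0.033 and 0.84 ± 0.033) rose. Of 23 integrated stress response genes, 18 fell at each dose and 5 and 4 rose (medians -0.52 and -0.72, camera adjusted p = 0.00115 and 0.00164; adjusted p = 0.0458 and 0.0581 with an estimated correlation). NUPR1, a stress-induced chromatin protein, fell from 156 ± 13.2 to 4.42 ± 2.22 and 1.48 ± 2.56 normalized counts (SD, n = 3). SLC7A11, the cystine transporter, fell from 2289.5 ± 178 to 405 ± 15.3 and 349 ± 28.7, and STC2 from 2815 ± 80.1 to 695 ± 55.8 and 462 ± 22.3. Of 19 heat shock genes, 6 rose and 8 fell at 0.5 µM and 5 rose and 8 fell at 1.5 µM (camera adjusted p = 0.646 and 0.643). Their medians were -0.027 and 0.0024, the latter with a mean of -0.12 and camera direction down, and with -2e-04 under TMM, -0.048 under upper-quartile scaling and -0.098 on FPKM values. HSPB1 (-1.52 ± 0.050 and -1.84 ± 0.050) fell and HSPA4L (0.51 ± 0.033 and 0.68 ± 0.033) rose. HSPE1 had -0.49 ± 0.12 and -0.75 ± 0.12, the first of them -0.441 with adjusted p = 0.0861 on FPKM values (range over the alternatives 1.66e-08 to 0.0861). Of 42 lysosome and autophagy genes, 21 rose and 8 fell at 0.5 µM and 22 rose and 10 fell at 1.5 µM (medians 0.092 and 0.12, the latter -0.0016 on FPKM values; camera adjusted p = 0.0698 and 0.0843). NEU1 (0.94 ± 0.028 and 1.08 ± 0.028) and ULK1 (0.90 ± 0.041 and 1.02 ± 0.041) rose and CTSZ (-0.94 ± 0.13 and -1.15 ± 0.13) fell.

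Of 19 genes of MHC class I antigen presentation, 14 fell at each dose and 1 and 2 rose (medians -1.03 and -0.96, camera adjusted p = 0.000564 and 0.00164; adjusted p = 0.0458 and 0.0729 with an estimated correlation). NLRC5, the transactivator of these genes, fell from 478 ± 22.0 to 103 ± 18.96 and 108 ± 9.55 normalized counts (SD, n = 3). The peptide transporter subunit TAP2 fell from 1340.1 ± 46.5 to 342 ± 39.9 and 341 ± 36.7, and ERAP2 from 76.4 ± 10.6 to 16.8 ± 6.26 and 10.5 ± 4.80. Of 22 type I interferon response genes, 15 fell at each dose and 5 and 6 rose (medians -0.91 and -0.80, camera adjusted p = 0.0295 and 0.0513; adjusted p = 0.104 at 0.5 µM with an estimated correlation). XAF1 (-2.41 ± 0.21 and -2.35 ± 0.21, SE), OAS3 (-2.02 ± 0.12 and -2.17 ± 0.12) and IFIH1, a sensor of double-stranded RNA (-1.73 ± 0.050 and -2.25 ± 0.050), fell. Of 12 NF-kappa B inflammatory genes, 9 fell and 2 rose at each dose (medians -0.92 and -0.88, camera adjusted p = 0.0295 and 0.0513; adjusted p = 0.138 at 0.5 µM with an estimated correlation). The chemokine CXCL1 fell from 272 ± 5.11 to 12.7 ± 3.04 and 9.65 ± 7.64 normalized counts. IL8 fell from 89.2 ± 5.17 to 4.75 ± 3.38 and 1.96 ± 0.163, and CXCL3 from 148 ± 12.1 to 30.3 ± 10.4 and 23.0 ± 5.27. Of 22 immediate early genes, 13 and 12 rose and 6 fell at each dose (medians 0.20 and 0.21, camera adjusted p = 0.144 and 0.146). EGR1 rose (1.91 ± 0.17 and 2.53 ± 0.17), and ZFP36 (-1.20 ± 0.13 and -1.64 ± 0.13) and NR4A3 (-1.69 ± 0.14 and -1.48 ± 0.14) fell.

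Markers of other cell types and of RNA quality were followed in the same way. All 7 tested epithelial lineage markers fell at both doses (medians -1.31 and -1.79, camera adjusted p = 0.000873 and 0.000903; adjusted p = 0.104 and 0.11 with an estimated correlation). KRT19 is among them (-1.52 ± 0.033 and -1.88 ± 0.033, SE, n = 3). Of 6 fibroblast markers, 2 fell at 0.5 µM and 3 at 1.5 µM, and none rose by limma, with 0 higher at an unadjusted p under 0.05 (medians -0.65 and -0.14, camera adjusted p = 0.221 and 0.281). COL3A1, a member chosen after its values were seen, moved with the 3 libraries that held H19 and SLC2A3 (1147, 1107 and 1022 normalized counts), while COL1A2, another collagen of this list, fell (-1.22 ± 0.086 and -1.36 ± 0.086). Of 2 tested immune markers 1 fell at each dose, CD14, and the endothelial marker CLDN5, the 1 tested, fell at both. Of 15 mitochondrially encoded genes, 1 and 3 rose and none fell by limma, with 0 lower at an unadjusted p under 0.05 (medians 0.050 and 0.056, with -0.0038 at 0.5 µM under upper-quartile scaling; camera adjusted p = 0.653 and 0.355). Adjusted over the list alone, the counts were the same as over all genes at both doses, except as follows. At 0.5 µM, the counts higher and lower adjusted over the list alone were 13 and 17 for neuronal transcription factors, 21 and 19 for effector genes, 15 and 5 for BET and elongation genes, and 2 and 40 for nucleolar genes. Adjusted over the list alone, they were 24 and 7 for G2 and mitosis genes, 11 and 5 for p53 targets, 6 and 53 for ribosomal proteins, 39 and 0 for histones, and 0 and 0 for mitochondrial genes (1 and 0 at an unadjusted p under 0.05). At 1.5 µM, they were 5 and 18 for stress response genes, 14 and 6 for immediate early genes, 5 and 16 for mesenchymal genes, and 2 and 0 for mitochondrial genes, each adjusted over the list alone.

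The comparison of 1.5 µM with 0.5 µM JQ1 asked which genes respond further to the higher dose. HEXIM1 rose further (log2 fold change 0.35 ± 0.032, SE, n = 3, limma adjusted p = 0.000279). So did BCL2L11 (0.21 ± 0.040), BRD2 (0.12 ± 0.035), HIST1H2BD (0.47 ± 0.055), TEX14 (0.71 ± 0.13) and BRCA2 (0.32 ± 0.047). The sum of the near-identical HIST2H4A and HIST2H4B went from 4605 ± 107 to 6703.5 ± 63.6 normalized counts (SD). MYC (-0.19 ± 0.024), DLL3 (-0.37 ± 0.048), SSTR2 (-0.37 ± 0.042), DDC (-0.53 ± 0.035) and IFIH1 (-0.52 ± 0.050) fell further. NEUROD1 (0.040 ± 0.028, adjusted p = 0.378) did not differ between the doses by this test. NWD1, a nucleotide-binding domain gene, fell from 62.4 ± 4.57 to 19.5 ± 5.78 normalized counts (SD; log2 fold change -1.67 ± 0.19, adjusted p = 0.000728).

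In total 2233 genes differed between the doses (limma, Benjamini-Hochberg adjusted p under 0.05), 816 higher and 1417 lower at 1.5 µM, of which 8 and 32 by at least 2-fold. Of the genes that differed, 36.5% were higher, and 19.5% of the 892 called on FPKM values. The libraries did not overlap in 33.7% of the tested genes, against 10% by chance. Of the 1417 genes lower at the higher dose, 1275 were also below DMSO at 0.5 µM, and of the 816 higher, 743 were also above it. The count depended on single libraries: it was 1473 without DMSO replicate 2, 1327, 1002 and 1023 without 1.5 µM replicates 1, 2 and 3. It rose to 3217 without 0.5 µM replicate 2, although fewer samples were left. It was 48, all lower, without the 3 libraries that held H19 and SLC2A3, which leaves 3 libraries for the doses together. Every one of the 9 ways to leave out 1 library at 0.5 µM and 2 at 1.5 µM gave 30 to 1230 genes, with a median of 103.

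Besides NWD1, the largest differences between the doses under the naming rule were those of HIST2H2BC (1.198 ± 0.26, SE, limma adjusted p = 0.0144), LINC00910 (1.09 ± 0.21, adjusted p = 0.0104) and TBC1D10C (0.77 ± 0.16, adjusted p = 0.0137), which were higher. KRT15 (-1.34 ± 0.20, adjusted p = 0.00251) and SH3TC1 (-1.27 ± 0.30, adjusted p = 0.0232) were lower. None of these 6 passed without the 3 libraries that held H19 and SLC2A3, where fewer samples are left and adjusted p ran from 0.0524 (NWD1) to 0.292 (TBC1D10C). The log2 fold changes were then 1.294 for HIST2H2BC, 1.03 for LINC00910, 0.793 for TBC1D10C, -1.121 for SH3TC1, -1.29 for NWD1 and -0.778 for KRT15. On FPKM values NWD1 (-0.71, adjusted p = 0.11), KRT15 (-0.67, adjusted p = 0.0804), SH3TC1 (-0.47, adjusted p = 0.436) and TBC1D10C (0.62, adjusted p = 0.155) did not pass. With 1 library left out, some calls crossed the threshold while the log2 fold changes stayed close. HIST2H2BC had 1.18 and 1.135 without 1.5 µM replicates 1 and 3 (adjusted p = 0.0525 and 0.0643), and SH3TC1 -1.223 without 0.5 µM replicate 1 (adjusted p = 0.059). TBC1D10C had 0.736, 0.785 and 0.791 without 1.5 µM replicates 1, 2 and 3 (adjusted p = 0.0556, 0.0559 and 0.0517). Over all alternatives the adjusted p ranged from 8e-10 to 0.11 for NWD1, 1.4e-07 to 0.107 for KRT15, 9.69e-05 to 0.436 for SH3TC1, 0.000298 to 0.292 for TBC1D10C, 6.41e-06 to 0.281 for HIST2H2BC and 1.5e-05 to 0.147 for LINC00910.

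Of the lists, 7 passed camera between the doses, 4 up and 3 down. Histone genes rose further, with 16 of 40 higher and none lower by limma, also at an unadjusted p under 0.05 (19 and 0 adjusted over the list alone; median log2 fold change 0.46, camera adjusted p = 1.7e-12; adjusted p = 0.0282 with an estimated correlation). Of the 11 genes reported to rise under BET inhibitors, 6 were higher (9 adjusted over the list alone; median 0.32, camera adjusted p = 2.46e-08; adjusted p = 0.156 with an estimated correlation). Of the cholesterol synthesis genes, 4 of 25 were higher (median 0.048, camera adjusted p = 0.0168; adjusted p = 0.156 with an estimated correlation). Of the homologous recombination and checkpoint genes, 5 of 28 were higher (8 adjusted over the list alone; median 0.046, camera adjusted p = 0.0376; adjusted p = 0.476 with an estimated correlation). Epithelial markers were lower in 4 of 7 (5 adjusted over the list alone; median -0.36, camera adjusted p = 0.00155; adjusted p = 0.194 with an estimated correlation). Secretory and neuronal effector genes were lower in 11 of 47 and higher in 3 (17 and 4 adjusted over the list alone; median -0.056, camera adjusted p = 0.00754; adjusted p = 0.27 with an estimated correlation). Nucleolar genes were lower in 5 of 43 and higher in 1 (10 and 1 adjusted over the list alone; median -0.057, camera adjusted p = 0.0168; adjusted p = 0.374 with an estimated correlation). The list of homologous recombination genes did not pass without 0.5 µM replicate 1 (adjusted p = 0.144) or 3 (0.237) or 1.5 µM replicate 2 (0.0714), within a range of 0.00138 to 0.476 over the alternatives. The other 21 lists tested by camera did not pass (adjusted p from 0.0907 to 0.854). Among them the heat shock (-0.0086) and interferon (-0.0011) medians were negative with camera direction up. The mesenchymal (median -0.046) and fibroblast lists (median -0.036) had means of 0.073 and 0.59 with camera direction down. COL3A1 and LUM of the fibroblast list, chosen after their values were seen, moved with the 3 libraries that held H19 and SLC2A3. In 0.5 µM replicate 3 and 1.5 µM replicates 1 and 2, LUM had 366, 252 and 287 normalized counts. The other JQ1 libraries held 1.17 to 4.15 normalized counts of LUM. Without the 3 libraries that held H19 and SLC2A3, the effector (0.0685), nucleolar (0.0669), cholesterol (0.0669) and homologous recombination (0.175) lists had adjusted p above the threshold. Over the alternatives the adjusted p ranged from 0.000394 to 0.27, 0.00241 to 0.374, and 0.00122 to 0.156 for the first 3 of these lists.

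The overlap of the doses was taken to ask how far both act on shared genes. CDH19, LOXL4, TP63 and SLC38A5 fell and HEXIM1, TEX14 and HIST1H2BD rose at both doses. Of the genes called against DMSO, 5823 were higher at both doses, where independent calls would give 2280, and 5593 were lower at both, where they would give 2201. Only 2 genes were called in opposite directions. A further 837 were called at 0.5 µM alone and 1388 at 1.5 µM alone, and of these 39 and 127 differed between the doses by the direct limma test. Of the 11416 genes called in the same direction at both doses, 9373 did not differ between the doses by that test. The median ratio of the log2 fold change at 1.5 µM to that at 0.5 µM was 1.17 over these 11416. Across genes, which are not independent replicates, the log2 fold changes of the doses had a Pearson correlation of 0.954. Both comparisons use the same 3 DMSO libraries, and in 20 simulations of unchanged groups set against shared controls the correlation was 0.484 and the covariance 0.0181, against 0.792 in the data. The highest count of genes called in the same direction in these simulations was 0 by limma, and 213 at an unadjusted p under 0.05. Part of the excess over independent calls may come from the shared controls, which are too few to be split.

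**Figure D3:**
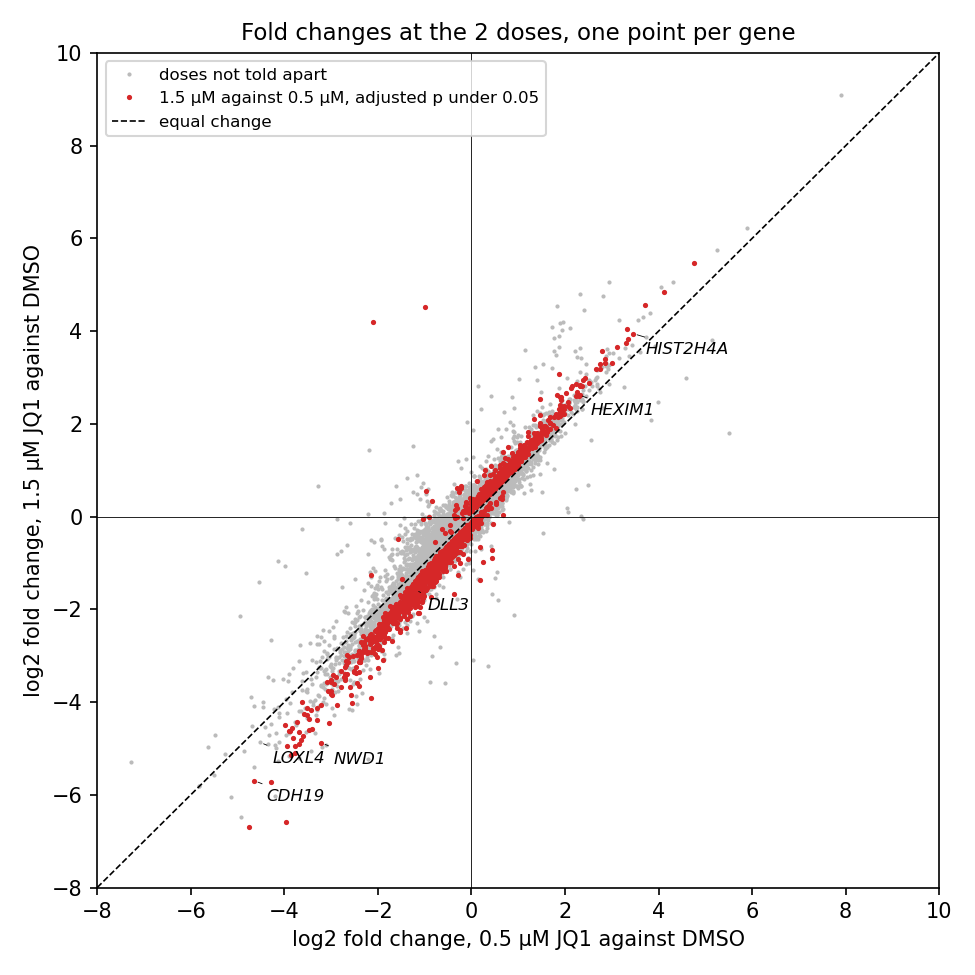
Log2 fold change against DMSO at 1.5 µM JQ1 (y axis) and at 0.5 µM JQ1 (x axis), one point per tested gene, with the dashed line at equal change and red points for the 2233 genes that differed between the doses (limma adjusted p under 0.05). HEXIM1 lies at 2.29 and 2.63, and NWD1 at -3.21 and -4.88.

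**Figure D4:**
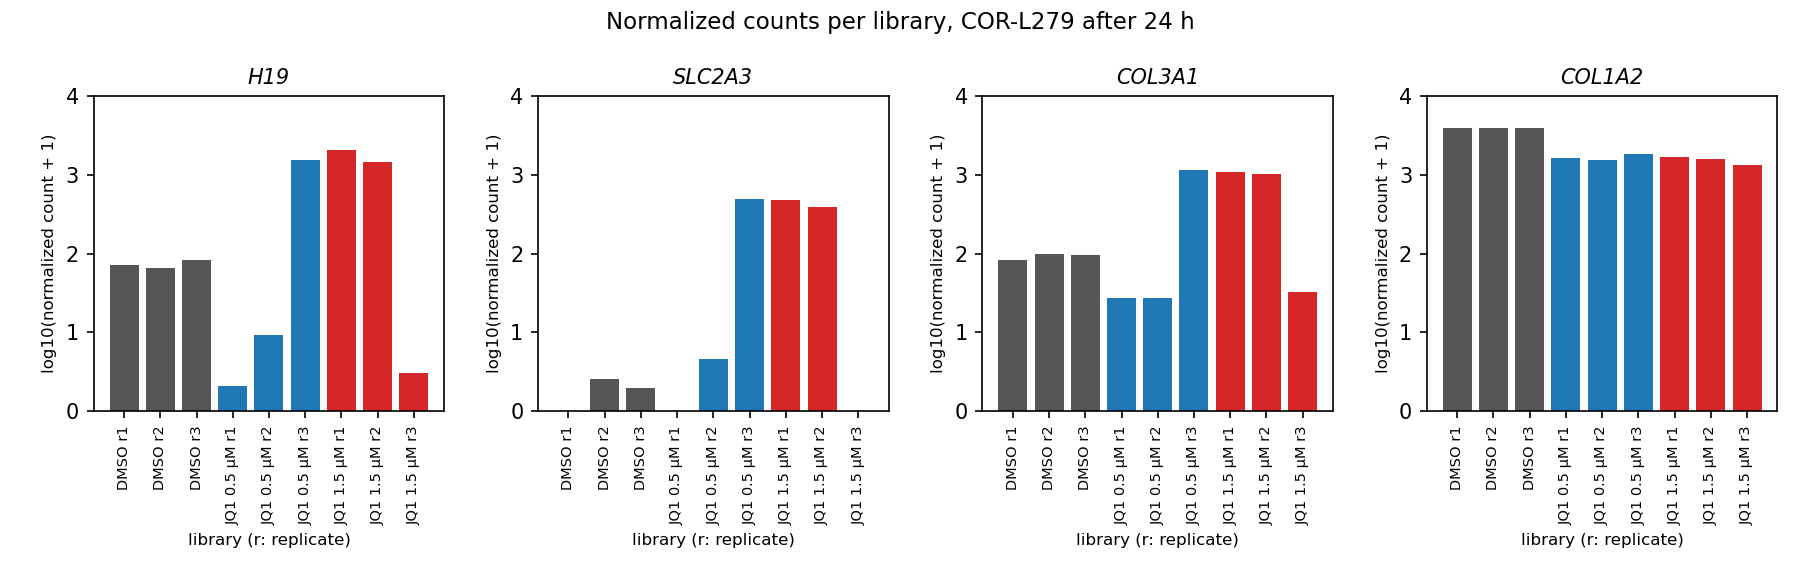
Normalized counts of H19, SLC2A3, COL3A1 and COL1A2 (y axis, log10 of the count + 1, bars from 0) in each of the 9 libraries (x axis; grey DMSO, blue 0.5 µM, red 1.5 µM JQ1). SLC2A3 stood at 489, 479 and 390 in 0.5 µM replicate 3 and 1.5 µM replicates 1 and 2 and at no more than 3.52 in the other libraries.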

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

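The test of genes outside the normalized count table was chosen only after the values of the named genes were seen. Of 40302 genes that appear with FPKM values alone, 727 had a mean of at least 1 FPKM in the DMSO or the JQ1 libraries, and 53 of these lay above every DMSO library in all 6 JQ1 libraries, while 68 lay below. Chance gives 1.19% in each direction. Among the 53, picked after their values were seen, are the histone gene HIST1H4D (mean 0.16 FPKM in DMSO and 1.07 after JQ1), the linker histone pseudogene HIST1H1PS1 (0.153 and 4.16) and RNU1-60P, annotated as a pseudogene of the U1 spliceosomal RNA (0.933 and 7.67). They drew attention because they have no normalized counts: the genes with FPKM values alone entered the tests only through the alternative on FPKM values, where they passed its minimum. No explanation was tested for them.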

How the results depend on the processing

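Among these alternatives, the fit without the 3 libraries that held H19 and SLC2A3 (0.5 µM replicate 3, 1.5 µM replicates 1 and 2) was chosen after seeing the data. Over all alternatives, the genes changed numbered 10886 to 13836 at 0.5 µM and 10615 to 14528 at 1.5 µM, and those shared in direction 9576 to 13121. The genes that differed between the doses numbered 892 on FPKM values, 5238 with arrayWeights and 1123 with only the 6 libraries compared. They numbered 1002 to 3217 with 1 library left out, the highest without 0.5 µM replicate 2, and 48 without the 3 libraries, where fewer samples are left. Leaving out 0.5 µM replicate 2 raised the count from 2233 to 3217 although fewer samples were left, so this library lowered it in the main fit. Apart from this and the other fits with fewer samples, the cause was not tested. edgeR called 12240, 12897 and 2283 genes and shared 12162, 12756 and 2196 with limma in direction, and DESeq2 called 12161, 12808 and 2853 and shared 12028, 12650 and 2164.

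With a replicate block, 12329, 12852 and 2030 genes were called. The labels do not say whether the replicate numbers mark pairs. Once group means were removed, DMSO and JQ1 libraries of the same number correlated at 0.036 to 0.243 across genes. In each JQ1 group, every DMSO library correlated most with the library of its own number. Between the JQ1 doses, libraries of the same number correlated at -0.456 to -0.148. Whether the numbers mark pairs stays open. Gene lists called fell from 13, 8 and 7 to 5, 1 and 1 with an estimated correlation, and fry, which does not compare a list with other genes, called 25, 26 and 13. Without the 3 libraries, 4 lists were called between the doses. Lists were not tested with edgeR or DESeq2. Of the named gene results under these alternatives, 5584 kept direction and side of the threshold, 37 lost the call, 13 gained one and 12 changed sign. INSM1, not called and near 0, changed sign on FPKM values (-0.038 and -0.053), under upper-quartile scaling (-0.051 and -0.044) and at 0.5 µM without the 3 libraries (-0.015), and ranged from -0.031 to 0.056 and from -0.009 to 0.024 with 1 library left out; the cause was not tested. YAP1 at 1.5 µM had -0.569 without the 3 libraries, in which it was high.

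Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. The real split was the 1 that called the most genes in each: 11663 at 0.5 µM and 14022 at 1.5 µM, where no other split called any by limma (at most 209 and 57 at an unadjusted p under 0.05), and 1123 between the doses, where the highest other called 57. The genes tested are limited by the 0.5 CPM in at least 2 libraries that every gene of the deposited table reached, while the minimum of 10 normalized counts left out 4.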

Other observations

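The gene lists of the next paragraph were written after the data were seen, and the tests of COL1A1, of the histone share of reads, of the S phase list, of pseudogenes and of transcript length as the whole cause were chosen only after the result was seen.

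Sodium, calcium and potassium channel genes, taken by their SCN, CACN and KCN symbols, fell as a list at 1.5 µM JQ1: of 77 tested, 50 fell and 17 rose by limma (median log2 fold change -0.72, camera adjusted p = 0.000516; adjusted p = 0.225 with an estimated correlation). The calcium channel genes CACNA1A (-4.37) and CACNG6 (-4.81) fell. Of 30 collagen genes, 19 fell and 3 rose (median -0.88, camera adjusted p = 0.00188; adjusted p = 0.225 with an estimated correlation), among them COL17A1 (-4.24), a collagen of epithelial anchoring. Of 21 pancreatic endocrine genes, 13 fell and 4 rose (median -0.28, camera adjusted p = 0.0276; adjusted p = 0.225 with an estimated correlation); GIPR, an incretin receptor (-1.81), and KCNJ11, a potassium channel on both lists (-1.66), fell. Zinc finger genes named ZNF rose as a list, 241 of 468 higher and 134 lower (median 0.19, camera adjusted p = 0.0276; adjusted p = 0.248 with an estimated correlation). Protocadherin genes (9 rose and 21 fell of 41; camera adjusted p = 0.102) and solute carrier genes (73 rose and 109 fell of 228; camera adjusted p = 0.102) did not pass. The genes named here were chosen after their values were seen.

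By gene type, 313 of 792 genes annotated as antisense rose at 1.5 µM and 154 fell (median log2 fold change 0.24), with the strand setting of the counting not given, and 75 of 1093 processed pseudogenes rose and 198 fell (median -0.25). Of 13750 protein-coding genes, 5433 rose and 5507 fell.

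In 0.5 µM replicate 3 and 1.5 µM replicates 1 and 2, 39 genes, H19, SLC2A3, GABRP, CGA and LUM among them, had at least 30 normalized counts and at least 3 times the highest other library; they summed to 118, 130.3 and 102 ppm of the normalized counts against 2.95 to 6.20 ppm in the other 6 libraries. An exchange of labels between the doses is argued against by the position of 0.5 µM replicate 3, 0.247 on a scale from the other 0.5 µM libraries (0) to the 1.5 µM libraries (1). For RNA of fibroblasts the values were mixed. COL1A1 did not rise: its lowest FPKM in the 3 libraries was 0.6 of the highest in the other JQ1 libraries. It is 1 gene with low values, at 0.24 to 0.48 FPKM. Of 11 fibroblast genes, 3 (27.27%; COL3A1, DCN and LUM) were highest in the 3 libraries. That share is no lower than the one of the trophoblast list below, so the lists do not tell these sources apart. RNA of a trophoblast-like human cell may be a source: of 32 trophoblast list genes at 0.05 FPKM or more, 21.88% (7, ERVFRD-1, ERVW-1, GATA3, GCM1, PAGE4, TFAP2C and XAGE2) had their 3 highest values there, against 0 of 12 liver genes, 1.88% of all genes and 1.19% by chance, while 25 did not and COR-L279 expresses several of those 25 in all libraries. These 7 genes were low in the 3 libraries too, at 0.03 to 0.28 FPKM, except PAGE4 (0.89 to 1.47 FPKM). COL3A1, DCN and LUM had 0.4 to 4 FPKM there. CGA, CYP19A1 and H19 had been seen before the trophoblast list was written and are not on it. A response of these cultures to JQ1 or another change in them stays open as untested, and the libraries concerned cannot serve as a group of the study.

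Histone genes rose at both doses. Reads moved between near-identical copies are argued against by their summed share, 4.94 times as high at 1.5 µM as in DMSO. A bias toward short transcripts is argued against by 377 other genes of like effective length (median 485 against 470 for histone genes) and level, which had a median log2 fold change of -0.131. A larger share of cells in S phase would raise replication genes alike, and is argued against by their median of 0.067 (SD 0.431) beside 2.51 for histone genes. The comparisons with DMSO tested whether these transcripts differ with JQ1, the difference the design names. How JQ1 might raise them stays open as untested.

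At 0.5 µM, replicate 2 lay apart, with a root mean square deviation of 0.166 (log2) from its group median over 9248 genes at 1000 normalized counts or more, against 0.0314 to 0.0616 in the other 8 libraries, and of 0.185 against 0.0469 to 0.119 from the mean of the other 2 libraries of the group. Its lower depth is argued against by 0.5 µM replicate 3, of similar depth, whose deviation was 0.345 of it (0.641 from the mean of the other 2), and reads shifted to pseudogenes and read-through genes by a decrease of only 5.89% without them (5.35% from that mean). Its deviation fell with transcript length (Spearman correlation -0.421 across genes, which are not independent), so a length bias may contribute, but DMSO replicates 1 (-0.64) and 3 (0.658) had stronger relations without lying apart. With the length trend removed its deviation was still 2.61 times the highest of the other 8 (1.59 times from the mean of the other 2), which argues against length as the whole cause. What set this library apart stays open, and no biological explanation was tested.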
